A study of Arabidopsis thaliana with 96 samples.

How the data were processed

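RNA sequencing measured polyadenylated transcripts in leaf discs of single Arabidopsis thaliana Col-0 plants, 1 library per plant, in 12 groups made of 3 light levels (low, mid and high) and 4 nitrate doses (2, 5, 10 and 20 mM) with 8 plants each. The light level, nitrate dose and replicate number of each of the 96 libraries were taken from the sample titles, and the library code that names its column in the count table from the sample descriptions, with 0 columns left without a group. The experiment also recorded growth, photosynthesis, pigments and elements, which were not analysed here.

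The deposited values are raw read counts per gene, 1 column per library, in whole numbers. Per the labels' protocols the libraries were made with the Kapa stranded mRNA kit, and per the submitters' processing notes the authors aligned reads with STAR 2.5.3a to the TAIR10 genome and counted them with featureCounts. The version of featureCounts, its strand setting, the annotation release and any filter are not given in the sources used here. Genes with near-identical copies (LHCB1.1, LHCB1.2 and LHCB1.3, the RBCS1B, RBCS2B and RBCS3B group, MYB113 and MYB114, and NRT2.1 and NRT2.2) are therefore uncertain one against another, and with no strand setting given, overlapping and antisense genes cannot be told apart. Counts scaled to a library total of 1000000 (CPM), log2 changes and percent shares were computed here from the deposited counts. Genes carry the locus names of the table. Symbols came from the RefSeq gene table of assembly TAIR10.1, to which 32548 of 32833 loci matched, and no coordinates were used.

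Total counts per library ran from 9.46 to 18.1 in units of 1000000 counts (median 12.5), and 20504 to 22239 genes had counts in a library. In the 336 pairs of libraries within groups the lowest chi-square per degree of freedom was 6.95 (median 68.5), so no 2 columns of a group were copies of one another. Pairs from different groups were not checked. The common biological coefficient of variation was 0.424 and the TMM factors ran from 0.766 to 1.35. On simulated counts in which 67, 67 and 66 genes per comparison changed by a log2 of 0.5, 1 and 2, the fit recovered 85.1%, 95.5% and 100% for high against low light, 76.1%, 91.0% and 95.5% for 20 against 2 mM nitrate, and 17.9%, 56.7% and 90.9% for the difference of the nitrate change between high and low light, with 22, 10 and 7 calls among 18898 unchanged genes. The simulation lacks the variation that libraries share, and only genes with a mean of at least 5 CPM were changed, so real performance can be worse.

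The main design and its tests, the alternatives below unless marked as added, the gene lists and the rule for naming genes were chosen before the data were examined. Genes were kept by filterByExpr with the group as factor, which left 19498 of 28025 genes with any count. The counts were scaled with TMM and fitted with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood method, with a mean for each of the 12 groups and 84 residual degrees of freedom. Light contrasts averaged the 4 doses, nitrate contrasts averaged the 3 light levels, and further contrasts compared doses within a light level, light levels at 2 and 20 mM, and the 20 against 2 mM change in high against low light. A single F test covered all 6 interaction terms. Calls have a Benjamini-Hochberg adjusted p under 0.05 over the tested genes, and adjusted p-values of genes are from edgeR unless another tool is named. The SE of a log2 change is its size divided by the square root of F.

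The 25 gene lists, with 373 different genes named from general knowledge of Arabidopsis, were fixed by symbol and locus. Of 377 list entries 351 have a symbol paired with the same locus in the reference table and 0 are contradicted by it. Each list was tested with camera at its preset correlation of 0.01 and with fry (limma 3.58.1), adjusted over the 25 lists. Beside each count of called members stands the count with p-values adjusted over the list alone. The genes named in the text follow 3 rules. First, for high against low light, 20 against 2 mM and their interaction, the 6 largest positive and 6 largest negative log2 changes among called genes with a symbol and a mean of at least 5 CPM, with the same sign at each of the doses or light levels. Next, from each list, up to 4 members with the smallest p. Last, NIA1, NIR1, NRT2.1, RBCS1A, CHS, ASN1 and PR1 in every case. A paragraph may name any subset of these.

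Shares of counts from the 133 chloroplast and 152 mitochondrial genes and from the 10 most abundant genes of each library were compared by two-sided permutation of labels within the strata of the other factor, with 100000 resamples, or with all assignments where n was under 10. Principal components were computed from log2 CPM. Library codes run consecutively through 4 blocks of 24 with 2 libraries of each group, a feature read from the codes, and whether these code sets mark a batch is not given in the sources used here. Labels were permuted in 24 further splits for each factor. The alternatives were RLE factors, no low-count filter, DESeq2 1.42.0, limma-voom with quality weights, a replicate block, a code set block, the compared groups alone, a trend over log2 of light or nitrate, and camera with an estimated correlation. Fits and share tests within each code set, comparisons of code sets with one another, leaving out code set 1, and leaving out each of 21 libraries that stood apart from their group, were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.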

Results

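Leaf discs of Arabidopsis thaliana Col-0, the standard laboratory accession, were taken from individual plants grown at 3 light levels and watered with 4 nitrate concentrations. Light was set at 100 (low), 250 (mid) or 500 (high) micromoles of photons per square metre per second, and nitrate at 2, 5, 10 or 20 mM. RNA from 8 plants was sequenced in each of the 12 combinations, which gave 96 libraries. The title of the series names the regulation that joins nitrogen use with photosynthesis as its question, and the crossed design asks how leaf transcripts respond to light, to nitrate and to both together. Total counts per library ranged from 9.46 to 18.1 in units of 1000000 counts, with a median of 12.5. Of 32833 loci, 28025 had a count in some library and 19498 had enough counts to be tested. Levels are given as counts scaled to a library total of 1000000 (CPM), and fold changes on the log2 scale with their standard error (SE) from the edgeR quasi-likelihood fit of all 96 libraries. The library codes in the labels form 4 runs of 24 consecutive codes, called code sets here. Each code set holds 2 libraries of every group, so values within the sets, computed after seeing the data, are given beside the pooled ones. Code set 1 differed from the other 3 in 13245 genes at adjusted p under 0.05. Without it, an alternative chosen after seeing the data, 13107 genes were called for light and 11904 for nitrate against 12192 and 12343 with all libraries.

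**Figure D1:**
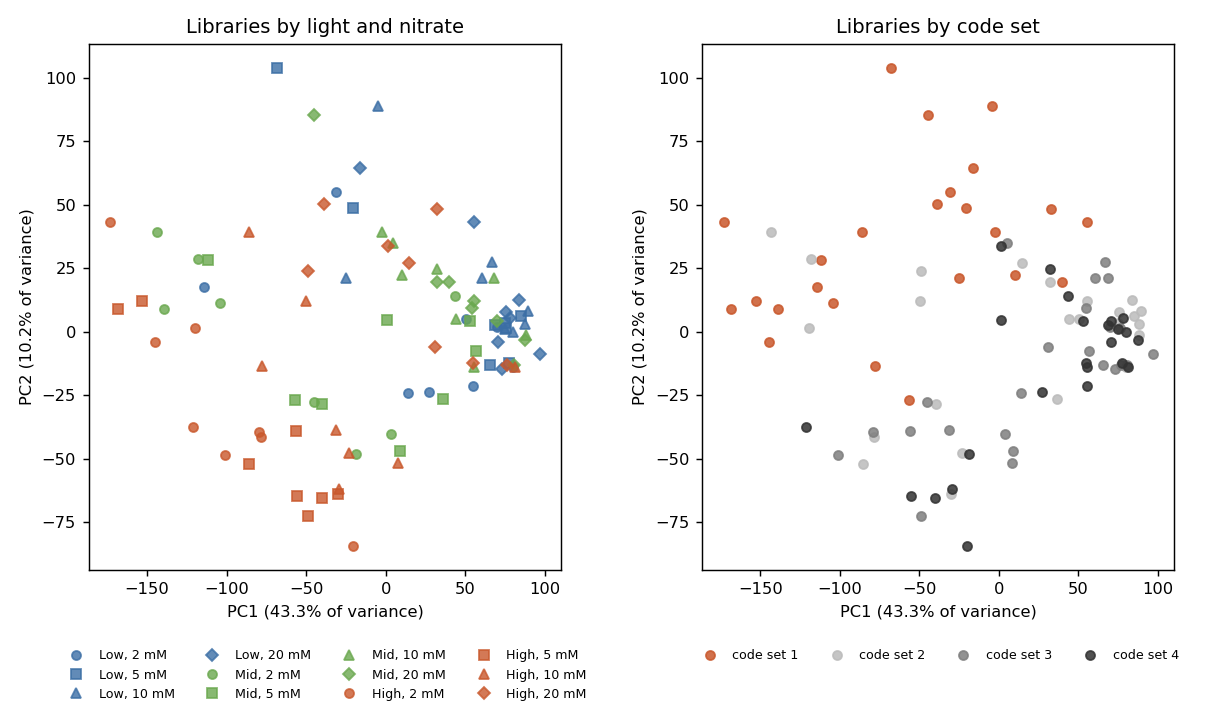
Each point is 1 of the 96 libraries on the first principal components of log2 CPM, which hold 43.3% (horizontal axis) and 10.2% (vertical axis) of the variance, with light level and nitrate dose marked on the left and code set on the right. On the horizontal axis the mean was 45.6 in low and -48.8 in high light, -50.3 at 2 and 42.4 at 20 mM nitrate, and -60.1 in code set 1.

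High light raised the genes of flavonoid and anthocyanin synthesis more than any other list of genes fixed before the data were examined. All 22 tested members rose between low and high light (averaged over the 4 nitrate doses, n = 32 libraries per level), with a median log2 change of 5.07. The transcript of DFR (AT5G42800), the reductase that opens the anthocyanin branch, rose by 7.86 ± 0.59 (adjusted p = 7.76e-20). At 2 mM nitrate its level was 3.80 ± 5.65 CPM in low and 487 ± 410 CPM in high light (mean ± SD, n = 8 each). CHS (AT5G13930), chalcone synthase, the first enzyme of the flavonoid pathway, rose by 4.03 ± 0.33 (adjusted p = 2.22e-18), from 34.3 ± 22.1 to 684 ± 589 CPM at 2 mM.

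The same list held most of the largest increases. LDOX (AT4G22880), which makes anthocyanidins, rose by 7.54 ± 0.53, the anthocyanin malonyltransferase gene 5MAT (AT3G29590) by 7.24 ± 0.49, the anthocyanin glycosyltransferase gene UGT79B1 (AT5G54060) by 6.28 ± 0.48 and the pathway regulator TT8 (AT4G09820) by 6.17 ± 0.47. The flavonoid hydroxylase genes F3'H (AT5G07990) and F3H (AT3G51240) rose by 5.40 ± 0.36 and 3.05 ± 0.21. The count adjusted over the list alone was also 22, and camera, which compares a list with all other genes, gave adjusted p = 4.83e-13. The list gave adjusted p = 0.301 with an estimated correlation. In 3 members a group had 0 counts in all 8 libraries, and with a floor of 3 counts over such a group the list median was 4.71.

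Averaged over the 4 nitrate doses, genes of the light-harvesting apparatus fell in high light. Of 20 antenna genes tested, 19 fell and 1 rose, and 29 of 31 nuclear genes for photosystem and electron transport subunits fell. All 15 genes of chlorophyll synthesis fell, and 13 of 18 Calvin cycle genes fell. LHCB2.1 (AT2G05100), an antenna protein gene of photosystem II, fell by 1.73 ± 0.16 (adjusted p = 1.28e-15). Its level at 2 mM nitrate was 3159 ± 1181 CPM in low and 604 ± 277 CPM in high light (SD, n = 8 each). At 20 mM its level was 4023 ± 579 CPM in low and 2736 ± 503 CPM in high light (SD, n = 8 each). At that dose RBCS1A stood at 19940 ± 3086 and 18150 ± 5351 CPM, and photosystem genes did not pass by edgeR. LHCB1.4 (AT2G34430) fell by 3.95 ± 0.44 and LHCB1.5 (AT2G34420) by 1.22 ± 0.12, while LHCB4.3 (AT2G40100) was the single member that rose, by 3.87 ± 0.23. In the photosystem I reaction centre PSAD1 (AT4G02770) fell by 1.1 ± 0.12 and PSAF (AT1G31330) by 1.26 ± 0.14. HEMA1 (AT1G58290), a gene of the chlorophyll synthesis list, fell by 1.45 ± 0.14. GUN4 (AT3G59400), an activator of magnesium chelatase, fell by 1.75 ± 0.15, and CAO (AT1G44446), which makes chlorophyll b, by 1.44 ± 0.12. RBCS1A (AT1G67090), a gene of the small Rubisco subunit, fell by 1.03 ± 0.17 (adjusted p = 2.1e-07) and GAPA2 (AT1G12900) by 1.26 ± 0.18. Adjusted over the list alone, 30 photosystem genes and 14 Calvin cycle genes fell and 1 Calvin cycle gene rose, with the same counts as above for the antenna and chlorophyll lists. By camera the 4 lists had adjusted p = 3.61e-10 (antenna), 4.83e-13 (photosystems), 1.2e-07 (chlorophyll) and 0.00299 (Calvin cycle). The values were adjusted p = 0.333 with an estimated correlation for the first 3 and 0.613 for the Calvin cycle.

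The share of counts from the chloroplast genome was also lower in high light. It was 2.36% ± 0.884 in high and 3.53% ± 0.539 in low light (SD, n = 32 each), a difference of -1.17 percentage points with p = 1e-05 in a two-sided permutation test, the smallest value that 100000 resamples can give (adjusted p = 1.5e-05 in a family of 6 tests). By code set the difference was -1.22, -1.38, -0.990 and -1.1 (n = 8 libraries per level, exact permutation p = 0.00309, 0.00154, 0.00154 and 0.0432). The 10 most abundant genes of each library took 6.29% ± 2.09 of the counts in high and 9.58% ± 1.53 in low light (p = 1e-05, permutation test, the smallest possible). The mitochondrial share was 0.183% ± 0.0404 and 0.177% ± 0.0649 and did not pass (permutation p = 0.596). Libraries of polyadenylated RNA should hold few chloroplast transcripts, so the chloroplast share can also follow RNA selection and quality. These were not told apart from expression.

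Nitrogen genes went both ways in high light. Of 26 tested genes for nitrate transport, sensing and nitrate-responsive regulators, 8 rose and 11 fell, and of 24 for nitrate reduction and ammonium assimilation, 12 rose and 11 fell, with the same counts adjusted over the list alone. There was no call for either list as a whole (camera adjusted p = 0.292 and 0.754). Averaged over the doses, the nitrate reductase gene NIA1 (AT1G77760) fell by 2.14 ± 0.30 (adjusted p = 4.2e-09) and the nitrite reductase gene NIR1 (AT2G15620) by 1.16 ± 0.17 (adjusted p = 1.51e-08). At 20 mM their means were not lower in high light. NIA1 stood there at 117 ± 30.5 CPM in low and 130 ± 66.9 CPM in high light, and NIR1 at 316 ± 48.5 and 455 ± 204 CPM (SD, n = 8 each). The regulators HHO2 (AT1G68670), LBD37 (AT5G67420) and BT2 (AT3G48360), known as nitrate-induced genes, fell by 1.73 ± 0.15, 2.33 ± 0.20 and 3.70 ± 0.56. GLT1 (AT5G53460), the NADH-dependent glutamate synthase, fell by 1.81 ± 0.14, while the cytosolic glutamine synthetase genes GLN1;4 (AT5G16570) and GLN1;1 (AT5G37600) rose by 2.97 ± 0.21 and 2.14 ± 0.23. CEPD1 (AT1G06830), a mobile signal of nitrogen demand, rose by 1.74 ± 0.16. ASN1 (AT3G47340), an asparagine synthetase gene induced in the dark, fell by 3.21 ± 0.47 (adjusted p = 1.28e-08). The transporter gene NRT2.1 (AT1G08090) lay near the detection floor and did not pass (log2 change -0.28 ± 0.53, adjusted p = 0.66).

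Among the remaining lists, 9 starch and sucrose genes rose and 3 fell of 15 (camera adjusted p = 0.00246, and adjusted p = 0.333 with an estimated correlation). APL3 (AT4G39210), a subunit of the starch-synthesis enzyme ADP-glucose pyrophosphorylase, rose by 1.65 ± 0.16. GBSS1 (AT1G32900), granule-bound starch synthase, rose by 2.17 ± 0.17 and GPT2 (AT1G61800), a plastid glucose-phosphate carrier, by 4.25 ± 0.36. Of 15 sugar starvation genes 10 fell and 3 rose (adjusted p = 0.00865, and adjusted p = 0.333 with an estimated correlation), with SEN1 (AT4G35770) at -3.15 ± 0.31 and bZIP1 (AT5G49450) at -1.39 ± 0.16. All 6 epidermis and cuticle markers fell (adjusted p = 0.00865, and adjusted p = 0.333 with an estimated correlation), among them CER1 (AT1G02205), which makes wax alkanes, at -3.40 ± 0.54 and ATML1 (AT4G21750), an epidermal identity factor, at -1.13 ± 0.13. Of 13 cell cycle genes 12 fell (adjusted p = 0.00299, and adjusted p = 0.573 with an estimated correlation), among them PCNA1 (AT1G07370) at -1.39 ± 0.23 and MCM5 (AT2G07690) at -0.93 ± 0.16, both parts of the DNA replication machinery. Of 12 clock genes 8 rose (adjusted p = 0.0397, and adjusted p = 0.333 with an estimated correlation), with PRR5 (AT5G24470) at 1.54 ± 0.27 and GI (AT1G22770) at 0.76 ± 0.10. Of 20 glucosinolate genes 12 fell and 1 rose (adjusted p = 0.0366, and adjusted p = 0.613 with an estimated correlation). CYP79B3 (AT2G22330) stood at -1.21 ± 0.20 and the regulator MYB51 (AT1G18570) at 1.55 ± 0.26. At 20 mM nitrate CYP79B3 had a mean of 238 ± 57.4 CPM in low and 284 ± 79.2 CPM in high light (SD, n = 8 each). Of 13 salicylic acid and defence genes 7 rose (adjusted p = 0.0454, and adjusted p = 0.613 with an estimated correlation), among them PAD4 (AT3G52430) at 1.11 ± 0.27 and WRKY70 (AT3G56400) at 1.09 ± 0.32. Adjusted over the list alone, all 7 counts were the same. The glucosinolate and salicylic acid calls ended with a replicate block (adjusted p = 0.0684 for both) and a code set block (0.0708 for both), and the clock call without code set 1 (0.118).

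The other lists made no call by camera for light. Photoprotection and stress genes rose in 9 and fell in 3 of 17 cases (10 and 3 adjusted over the list alone), with ELIP1 (AT3G22840), an early light-induced protein gene, up by 4.60 ± 0.39. Shade avoidance genes rose in 4 and fell in 6 of 13 cases, with the growth regulator gene PIF4 (AT2G43010) at -1.0 ± 0.11. Jasmonate and wounding genes rose in 1 and fell in 4 of 9, with PDF1.2 (AT5G44420) at 3.29 ± 0.59 and VSP2 (AT5G24770) at -1.49 ± 0.31. At 20 mM nitrate the mean of VSP2 was not lower in high light, with 3949 ± 2479 CPM in low and 6523 ± 2683 CPM in high light (SD, n = 8 each). Counts of genes that rose and fell were 8 and 2 of 13 for senescence and autophagy, 7 and 2 of 13 for phosphate starvation, 2 and 3 of 11 for photorespiration, 1 and 5 of 9 for cytokinin response, 0 and 0 of 5 for sulfur assimilation, 1 and 1 of 2 for floral transition and 3 and 4 of 8 for vascular markers, with the same counts adjusted over the list alone. For sulfur assimilation edgeR also gave 0 at unadjusted p under 0.05, and at adjusted p under 0.05 DESeq2 gave 0 and limma-voom 3. Guard cell and myrosin cell markers gave 1 and 1 of 7, and 1 and 0 adjusted over the list alone. For sulfur assimilation the list median (-0.06) and mean (-0.11) were negative where camera and fry pointed up, and for nitrate reduction the mean (-0.04) was negative where the median (0.07) and both tests pointed up. Outside the lists, the expansin gene EXPA8 (AT2G40610) and the gibberellin-responsive gene GASA6 (AT1G74670) fell by 3.63 ± 0.37 and 3.48 ± 0.36. The defence marker PR1 (AT2G14610) varied widely between plants of one group and did not pass (1.65 ± 0.83, adjusted p = 0.074), but it passed with a replicate block (4.19, adjusted p = 3.52e-05), a code set block (3.92, adjusted p = 6.93e-05), limma-voom (4.69, adjusted p = 9.39e-05) and without code set 1 (9.92, adjusted p = 3.81e-07). It also passed when single low-light libraries with high PR1 were left out: 3.74 (adjusted p = 0.00041) without the 10 mM replicate 2, 3.39 (0.00064) without the 2 mM replicate 2, 2.43 (0.021) without the 20 mM replicate 1 and 2.12 (0.024) without the 5 mM replicate 1. Leaving out a low-light library with high PR1 raises this change by construction, so these passes are no separate support for it.

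Over all genes, 12192 of 19498 (62.5%) passed between high and low light by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, of which 6596 were higher and 5596 lower in high light. Of these, 1365 rose and 1284 fell at least 2-fold. Within code sets 1 to 4, each with 8 libraries per light level, 4393, 10686, 7952 and 5858 genes passed. In set 1 more genes were lower (2472) than higher (1921), unlike in the pooled fit. In 25 fixed lists camera made 12 calls and the fry test 18. Under permuted light labels camera made a median of 6.5 calls, so its small p-values for lists call for caution. Fry tests whether the genes of a list move one way on balance, or change in either direction, and does not compare the list with other genes or sets. With an estimated correlation camera made 0 calls at adjusted p under 0.05 and 3 at unadjusted p under 0.05.

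The steps of light differed in their counts in the main fit. Between low and mid light 3854 genes passed (1988 higher, 1866 lower in mid light), and between mid and high light 7554 (4129 higher, 3425 lower). Flavonoid genes rose in both steps, with 18 of 22 past the test for mid against low (median log2 change 2.43, 19 adjusted over the list alone) and 22 of 22 for high against mid (median 2.17, 22 adjusted over the list alone). Cell cycle genes passed in 0 of 13 cases for mid against low by edgeR and fell in 10 of 13 for high against mid. Adjusted over the list alone the counts were the same. For mid against low edgeR gave 2 at unadjusted p under 0.05, and at adjusted p under 0.05 DESeq2 gave 0 and limma-voom 6. The difference between the steps was not tested. In code sets 1 to 4 taken singly, 218, 6767, 86 and 96 genes passed for mid against low and 486, 1861, 3379 and 1653 for high against mid. For high against mid the majority turned with the scaling, to 3628 higher and 3792 lower with RLE factors and 3794 and 3986 with DESeq2. It also turned without code set 1 (4421 and 4533) and within each code set (152 and 334, 888 and 973, 1554 and 1825, 703 and 950). For mid against low it turned within set 2 (3235 and 3532). The mid against low count was 5832 with a replicate block and 6834 without code set 1. Limma-voom called 8668 genes for mid against low and 8660 for high against mid, so the difference between the steps depends on the fit.

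**Figure D2:**
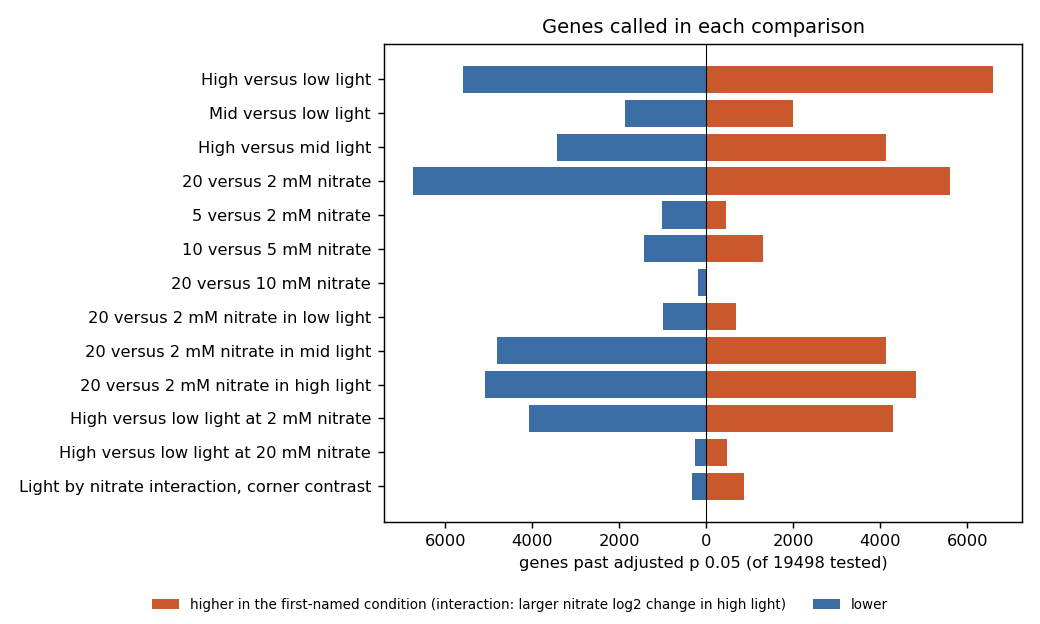
Horizontal bars give the number of genes past adjusted p 0.05, of 19498 tested, in each comparison, with genes that were higher and lower drawn apart as the legend states. The longest bars belong to 20 against 2 mM nitrate (12343) and high against low light (12192), and the shortest to 20 against 10 mM nitrate (214).

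On average over light, leaves at 20 mM nitrate had more transcript of photosynthesis genes and less of most flavonoid genes than leaves at 2 mM. Between 2 and 20 mM nitrate, averaged over the 3 light levels (n = 24 libraries per dose), 19 of 20 antenna genes, 31 of 31 photosystem and electron transport genes, 18 of 18 Calvin cycle genes and 14 of 15 chlorophyll genes rose, and 16 of 22 flavonoid genes fell. RBCS1A (AT1G67090) rose by 1.41 ± 0.20 (adjusted p = 5.27e-09), and its level in high light was 5168 ± 1757 CPM at 2 mM and 18150 ± 5351 CPM at 20 mM (SD, n = 8 each). DFR (AT5G42800) fell by 4.54 ± 0.61 (adjusted p = 2e-09) and CHS (AT5G13930) by 1.46 ± 0.34 (adjusted p = 0.00015). In high light the mean of CHS lay highest at 5 mM, with 684 ± 589, 1799 ± 682, 912 ± 573 and 273 ± 169 CPM at 2, 5, 10 and 20 mM (SD, n = 8 each), and the steps within high light were not tested. In low light CHS stood at 34.3 ± 22.1 CPM at 2 mM and 30.7 ± 18.8 CPM at 20 mM (SD, n = 8 each). By edgeR, photosystem genes passed in mid and high but not in low light. For 20 against 2 mM, 1695 genes were called in low against 9913 in high light.

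In the antenna LHCB2.1 (AT2G05100), LHCB3 (AT5G54270) and LHCB1.5 (AT2G34420) rose by 1.46 ± 0.18, 1.37 ± 0.20 and 1.02 ± 0.13. The ATP synthase gene ATPD (AT4G09650) rose by 1.44 ± 0.18 and the ferredoxin gene FD2 (AT1G60950) by 1.33 ± 0.18. In the Calvin cycle GAPA2 (AT1G12900) rose by 1.55 ± 0.21 and TKL1 (AT3G60750) by 0.84 ± 0.11, and in chlorophyll synthesis HEMA1 (AT1G58290), CRD1 (AT3G56940) and CAO (AT1G44446) rose by 1.31 ± 0.16, 1.25 ± 0.15 and 1.17 ± 0.14. Of 11 photorespiration genes 9 rose, among them GLDT (AT1G11860) at 1.04 ± 0.17 and GLYK (AT1G80380) at 0.78 ± 0.11. The flavonoid genes TT8 (AT4G09820), F3'H (AT5G07990) and F3H (AT3G51240) fell by 3.91 ± 0.52, 2.87 ± 0.38 and 1.84 ± 0.23, and the list median was -2.05, or -2.00 with the floor of 3 counts. The counts adjusted over the list alone were the same for these 6 lists. Camera gave adjusted p = 2.92e-10 for the antenna, 1.92e-15 for photosystems, 3.32e-10 for the Calvin cycle, 8.22e-08 for chlorophyll, 0.00397 for photorespiration and 0.011 for flavonoids. It gave adjusted p = 0.493 with an estimated correlation for the first 4, 0.565 for photorespiration and 0.583 for flavonoids. The chloroplast-encoded share of counts was 3.59% ± 0.681 at 20 mM and 2.52% ± 0.929 at 2 mM (SD, n = 24 each, difference 1.07, p = 1e-05, two-sided permutation test, the smallest possible, adjusted p = 1.5e-05). The 10 most abundant genes took 9.64% ± 1.13 and 6.05% ± 2.35 (p = 1e-05, permutation test), while the mitochondrial share was lower at 20 mM (0.172% ± 0.0333) than at 2 mM (0.222% ± 0.0715), with permutation p = 0.00344 (adjusted p = 0.00413). By code set the difference in the chloroplast share was 0.364, 0.977, 1.26 and 1.66 (n = 6 libraries per dose, exact permutation p = 0.380, 0.0463, 0.00926 and 0.00926). As for light, RNA selection and quality were not told apart from expression in this share.

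Genes of nitrate signalling and nitrogen assimilation went both ways. BT2 (AT3G48360) rose by 6.16 ± 0.67 (adjusted p = 5.61e-12), from 0.195 ± 0.171 to 52.3 ± 67.8 CPM in high light (SD, n = 8 each). LBD38 (AT3G49940), a regulator of nitrogen genes, rose by 3.18 ± 0.33, HHO2 (AT1G68670) by 1.64 ± 0.17, NIA1 (AT1G77760) by 2.7 ± 0.35 (adjusted p = 1.12e-09), NIR1 (AT2G15620) by 1.52 ± 0.20 (adjusted p = 1.08e-09) and GLT1 (AT5G53460) by 1.4 ± 0.16. GLN1;4 (AT5G16570) fell by 2.98 ± 0.24 and GLN1;1 (AT5G37600) by 2.1 ± 0.26. The amino acid breakdown genes THA1 (AT1G08630), for threonine aldolase, BCAT2 (AT1G10070), for a branched-chain aminotransferase, and PRODH1 (AT3G30775), for proline dehydrogenase, had log2 changes of -4.89 ± 0.51, -3.99 ± 0.59 and -1.31 ± 0.24. CEPD2 (AT2G47880) fell by 1.60 ± 0.17. ASN1 (AT3G47340) rose by 2.24 ± 0.52 (adjusted p = 0.000153), and by 2.90 without the mid-light 2 mM replicate 7. NRT2.1 (AT1G08090) did not pass (-0.10 ± 0.66, adjusted p = 0.903), nor did PR1 (AT2G14610, -1.56 ± 0.95, adjusted p = 0.146). PR1 passed with a code set block (-1.99, adjusted p = 0.0403), without the high-light 20 mM replicate 4 (-3.18, adjusted p = 0.0039) or the low-light 20 mM replicate 1 (-2.6, adjusted p = 0.040), and its sign turned to 0.75 without the low-light 2 mM replicate 2. These libraries had the highest PR1 of their groups, so the direction of each shift follows by construction. Of the nitrate transport and regulator list 10 rose and 8 fell of 26 (10 and 9 adjusted over the list alone), with a median of -0.02 where the mean (0.33) and both tests pointed up. Of the nitrate reduction and ammonium list 11 rose and 9 fell of 24, the same adjusted over the list alone, and camera made no call for either (adjusted p = 0.281 and 0.301).

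Growth, defence and sugar genes also moved. Of 13 cell cycle genes 12 rose (camera adjusted p = 4.32e-05, and adjusted p = 0.565 with an estimated correlation), among them PCNA1 (AT1G07370) at 1.81 ± 0.27 and the cyclin gene CYCB1;2 (AT5G06150) at 1.73 ± 0.28. Of 9 jasmonate and wounding genes 5 rose (adjusted p = 0.0232, and adjusted p = 0.577 with an estimated correlation). These included the vegetative storage protein genes VSP1 (AT5G24780) and VSP2 (AT5G24770) at 4.1 ± 0.62 and 2.72 ± 0.37, and the jasmonate synthesis genes LOX2 (AT3G45140) and AOS (AT5G42650) at 1.01 ± 0.18 and 0.80 ± 0.20. Of 20 glucosinolate genes 14 rose and 2 fell (adjusted p = 0.0151, and adjusted p = 0.583 with an estimated correlation), with CYP79B3 (AT2G22330) at 1.22 ± 0.23 and UGT74C1 (AT2G31790) at 0.76 ± 0.12. Of 15 sugar starvation genes 9 rose and 2 fell (adjusted p = 0.0415, and adjusted p = 0.565 with an estimated correlation). The sugar starvation, jasmonate and glucosinolate calls ended without code set 1 (adjusted p = 0.0888 for each), and the clock list, which had none, was called as lower with a replicate block (0.0449) and a code set block (0.0452). Outside the lists the germin-like gene GER3 (AT5G20630) rose by 3.39 ± 0.79. Of 9 cytokinin genes 5 rose and 1 fell, with the response regulators ARR9 (AT3G57040) at 1.23 ± 0.17 and ARR5 (AT3G48100) at 1.1 ± 0.25, but camera made no call (adjusted p = 0.176). The starch list also went both ways without a call, with 4 up and 7 down of 15, such as APL1 (AT5G19220) at 0.85 ± 0.12 and APL3 (AT4G39210) at -1.09 ± 0.18. Counts that rose and fell without a call were 4 and 5 of 17 for photoprotection, 2 and 4 of 13 for shade avoidance, 0 and 6 of 12 for the clock, 0 and 5 of 13 for senescence, 2 and 7 of 13 for phosphate starvation, 3 and 0 of 5 for sulfur, 0 and 1 of 2 for floral transition, 3 and 0 of 6 for the epidermis, 1 and 1 of 7 for guard and myrosin cells, with the myrosin cell enzyme gene TGG1 (AT5G26000) at 1.53 ± 0.43, and 4 and 2 of 8 for vascular markers. For guard and myrosin cells the median (-0.11) was negative where the mean (0.07) and both tests pointed up. Adjusted over the list alone these counts were the same, while the salicylic acid list had 4 of 13 genes that fell and 0 adjusted over the list alone.

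Over all genes 12343 of 19498 (63.3%) passed between 20 and 2 mM by edgeR's quasi-likelihood test (5597 higher, 6746 lower at 20 mM), with 1409 up and 1320 down at least 2-fold. Within code sets 1 to 4, each with 6 libraries per dose, 7705, 7611, 8369 and 3321 genes passed. In sets 1 and 2 more genes were higher (4046 and 4482) than lower (3659 and 3129), unlike in the pooled fit. Camera made 10 list calls and fry 20 of 25. Under permuted nitrate labels camera made a median of 6.5 calls. Camera with an estimated correlation made 0 calls at adjusted p under 0.05 and 1 at unadjusted p under 0.05.

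Step by step, 1470 genes passed for 5 against 2 mM (456 higher, 1014 lower), 2735 for 10 against 5 mM (1303 higher, 1432 lower) and 214 for 20 against 10 mM (26 higher, 188 lower). Photosystem genes rose in 3 of 31 cases from 2 to 5 mM (28 adjusted over the list alone), in 24 from 5 to 10 mM (30 adjusted over the list alone) and in 0 from 10 to 20 mM (0 adjusted over the list alone, and 0 at unadjusted p under 0.05 by edgeR). For 20 against 10 mM DESeq2 gave 0 and limma-voom 3 at adjusted p under 0.05. Flavonoid genes fell in 0, 5 and 10 of 22 cases over these steps (0, 6 and 14 adjusted over the list alone), and 2 rose from 2 to 5 mM, also 2 adjusted over the list alone. The differences between the steps were not tested. DESeq2 called 450 genes for 20 against 10 mM (116 higher, 334 lower), so that higher genes made up 25.8% of its calls and 12.2% of edgeR's. Higher and lower genes were 405 and 661 with a replicate block, 473 and 722 with a code set block and 1634 and 1476 with limma-voom, so the excess of lower genes depends on the fit. For 10 against 5 mM the majority turned, to 1530 higher and 1154 lower with RLE factors, 1841 and 1401 with DESeq2, 2421 and 2355 with a replicate block, 2488 and 2364 with a code set block and 1715 and 1364 without code set 1. For 5 against 2 mM it turned within sets 2 (1787 and 1191) and 3 (215 and 149), and limma-voom gave 2676 and 2747. By code set the counts were 0, 2978, 364 and 0 for 5 against 2 mM, 22, 29, 0 and 0 for 10 against 5 mM and 34, 1, 304 and 1 for 20 against 10 mM. For the sets with 0, the same test gave 1077 (set 1) and 738 (set 4) genes at unadjusted p under 0.05 for 5 against 2 mM, and 2239 (set 3) and 3525 (set 4) for 10 against 5 mM. Single libraries moved the counts by over 1.5 times. For 5 against 2 mM the count was 561 without the low-light 2 mM replicate 2, 2755 without the low-light 5 mM replicate 1, 3116 without the mid-light 2 mM replicate 7 and 2536 without the mid-light 5 mM replicate 2. For 10 against 5 mM it was 1227 without the high-light 10 mM replicate 8 and 1761 without the mid-light 5 mM replicate 2. For 20 against 10 mM it was 105, 117, 121 and 133 without the low-light 20 mM replicates 5 and 8 and 10 mM replicates 1 and 2, 123 without the mid-light 10 mM replicate 2, 134 without the high-light 10 mM replicate 2, 344 without the high-light 20 mM replicate 4, 368 without the low-light 20 mM replicate 1, 378 without the mid-light 20 mM replicate 5 and 1371 without the high-light 10 mM replicate 8. With a replicate block these counts were 3463, 4776 and 1066, and without code set 1 the 20 against 10 mM count was 0, with 2779 genes at unadjusted p under 0.05 by edgeR.

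The nitrate response differed between light levels. Tested as the difference between the 20 against 2 mM change in high light and that in low light, 1175 genes passed, of which 855 had the more positive nitrate change in high light and 320 the more negative. This split depends on the fit, with 3492 positive and 3350 negative by limma-voom and 762 and 1030 within code set 3. NIR1 (AT2G15620) rose from 46 ± 18.7 to 455 ± 204 CPM in high light and stood at 274 ± 120 and 316 ± 48.5 CPM in low light (SD, n = 8 each), a difference in log2 change of 3.1 ± 0.49 (adjusted p = 2.06e-05). GLN1;4 (AT5G16570) went from 296 ± 133 to 11.8 ± 6.84 CPM in high and from 18.9 ± 7.00 to 9.06 ± 2.36 CPM in low light (difference -3.59 ± 0.56, adjusted p = 2.02e-05). LHCB2.1 (AT2G05100) went from 604 ± 277 to 2736 ± 503 CPM in high and from 3159 ± 1181 to 4023 ± 579 CPM in low light (difference 1.83 ± 0.45, adjusted p = 0.00674).

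**Figure D3:**
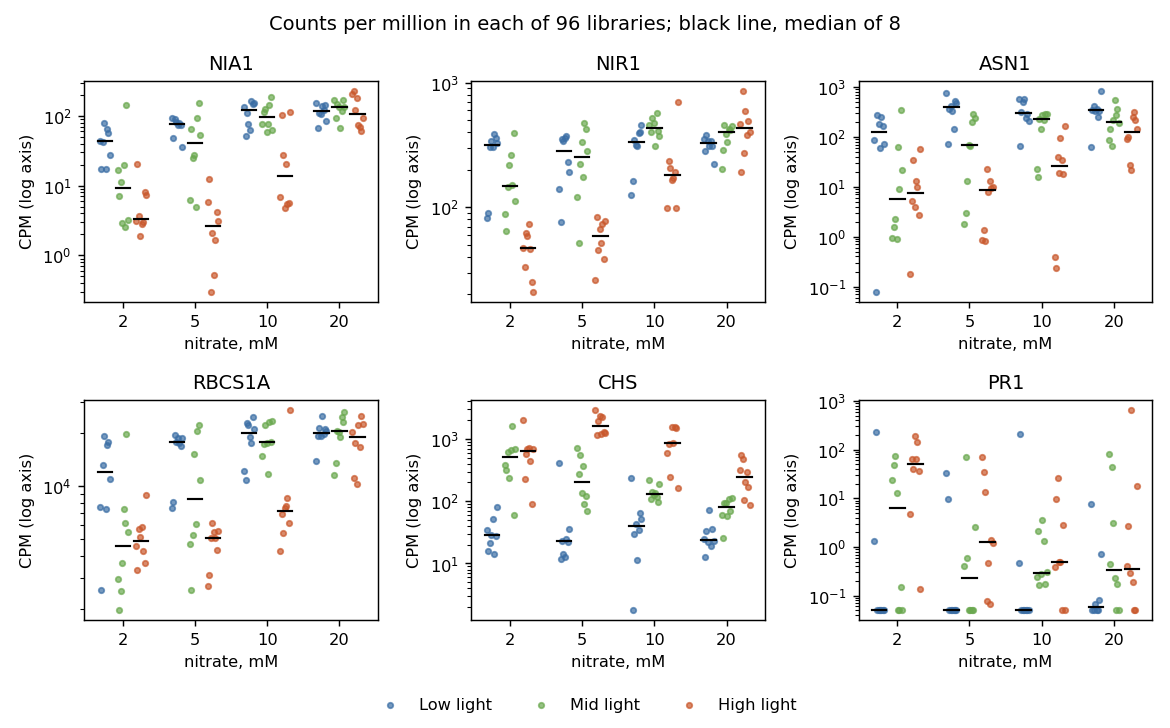
Points give the CPM of single libraries on a log axis for selected genes in the 12 groups of light and nitrate, with the black line at the median of the 8 libraries and values under 0.05 CPM drawn at 0.05. NIR1 in high light lay at a mean of 46 CPM at 2 mM and 455 CPM at 20 mM nitrate.

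Several nitrogen genes shared this pattern. The difference was 2.95 ± 0.83 for NIA1 (AT1G77760, adjusted p = 0.0211), 3.12 ± 0.77 for LBD38 (AT3G49940), 2.32 ± 0.55 for LBD37 (AT5G67420), 2.18 ± 0.42 for HHO2 (AT1G68670) and 1.71 ± 0.39 for GLT1 (AT5G53460). It was negative for PRODH1 (AT3G30775), at -2.44 ± 0.60, and for the peptide transporter gene OPT1 (AT5G55930), at -3.12 ± 0.71. Of the nitrate transport and regulator genes 5 of 26 had a positive and 1 a negative difference (8 and 2 adjusted over the list alone), and of the nitrate reduction and ammonium genes 7 and 2 of 24 (9 and 5 adjusted over the list alone), with no camera call for either list (adjusted p = 0.229 and 0.386). The amino acid transporter gene UMAMIT36 (AT1G70260) had a difference of 5.99 ± 0.99, with levels of 0.755 ± 0.508 and 14.6 ± 17.1 CPM in high light at 2 and 20 mM and of 6.57 ± 3.17 and 1.98 ± 1.68 CPM in low light, so changes of opposite sign make up the difference. NRT2.1 (AT1G08090, 2.51 ± 1.5, adjusted p = 0.329) and ASN1 (AT3G47340, 1.76 ± 1.23, adjusted p = 0.417) did not pass.

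Part of the photosynthesis genes had a more positive nitrate change in high light. The difference passed in 6 of 20 antenna genes (19 adjusted over the list alone), in 9 of 31 photosystem genes (26 adjusted over the list alone), in 3 of 15 chlorophyll genes (6 adjusted over the list alone), in 0 of 18 Calvin cycle genes and in 0 of 11 photorespiration genes (0 in both adjusted over the list alone). At unadjusted p under 0.05 edgeR gave 11 and 3 for these last lists. At adjusted p under 0.05 DESeq2 gave 0 and 0 and limma-voom 17 and 10. LHCB3 (AT5G54270) and LHCB1.5 (AT2G34420) had differences of 1.75 ± 0.49 and 1.23 ± 0.33, PSAE1 (AT4G28750) and PSAD1 (AT4G02770) of 1.39 ± 0.38 and 1.16 ± 0.33, and GUN4 (AT3G59400) and GLK1 (AT2G20570), a regulator of photosynthesis genes, of 1.66 ± 0.41 and 0.75 ± 0.22. Camera gave adjusted p = 5.67e-08 for the antenna, 8.79e-11 for photosystems, 0.00109 for chlorophyll and for the Calvin cycle and 0.0154 for photorespiration. It gave adjusted p = 0.592 with an estimated correlation for all but the Calvin cycle (0.658). RBCS1A (AT1G67090) did not pass (1.07 ± 0.47, adjusted p = 0.161). In high light the chloroplast-encoded share of counts was 1.67% ± 0.499 at 2 mM and 3.40% ± 0.862 at 20 mM, and in low light 3.43% ± 0.598 and 3.71% ± 0.484 (SD, n = 8 each). This share can also follow RNA selection and quality.

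Defence genes had some of the largest differences. Of 9 jasmonate and wounding genes 4 had a positive difference (4 adjusted over the list alone, camera adjusted p = 7e-05, and adjusted p = 0.468 with an estimated correlation). These were VSP1 (AT5G24780) at 5.94 ± 1.45, VSP2 (AT5G24770) at 3.89 ± 0.88, AOS (AT5G42650) at 1.90 ± 0.48 and LOX2 (AT3G45140) at 1.88 ± 0.45. VSP2 went from 182 ± 198 to 6523 ± 2683 CPM in high light and from 1631 ± 1219 to 3949 ± 2479 CPM in low light (SD, n = 8 each). Of 20 glucosinolate genes 10 had a positive difference (15 positive and 1 negative adjusted over the list alone, camera adjusted p = 1.3e-08, and adjusted p = 0.468 with an estimated correlation). Among them were the regulators MYB34 (AT5G60890) at 2.74 ± 0.57 and MYB29 (AT5G07690) at 2.39 ± 0.56 and the enzyme gene UGT74C1 (AT2G31790) at 1.31 ± 0.30. The terpene synthase gene TPS10 (AT2G24210) had the difference 6.59 ± 1.46. Of 13 salicylic acid genes 1, ICS1 (AT1G74710), which makes the precursor of salicylic acid, passed at -1.76 ± 0.40 (1 positive and 1 negative adjusted over the list alone). For this list camera and fry pointed down (camera adjusted p = 0.000286, and adjusted p = 0.592 with an estimated correlation). Its median was -0.19 but its mean 0.28. Of 13 cell cycle genes 0 passed by edgeR (5 at unadjusted p under 0.05), and at adjusted p under 0.05 DESeq2 gave 1 and limma-voom 7. Adjusted over the list alone 2 were positive (camera adjusted p = 0.000975, and adjusted p = 0.592 with an estimated correlation).

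In the flavonoid list 1 of 22 genes passed, also 1 adjusted over the list alone. This was F3'H (AT5G07990) at -3.26 ± 0.90, while CHS (AT5G13930) did not pass (-1.16 ± 0.82, adjusted p = 0.419). In mid light DFR (AT5G42800) stood at 347 ± 219 CPM at 2 mM and 1.45 ± 1.52 CPM at 20 mM. ELIP1 (AT3G22840) passed at -3.36 ± 1.02 (adjusted p = 0.033) but not with limma-voom (-2.11, adjusted p = 0.122), in the compared groups alone (-3.38, adjusted p = 0.082) or without code set 1 (-1.27, adjusted p = 0.38). The auxin transporter gene ABCB21 (AT3G62150) had the difference -3.37 ± 0.67 and PIF4 (AT2G43010) 1.07 ± 0.32. PR1 (AT2G14610) did not pass (5.06 ± 2.43, adjusted p = 0.207). Its sign turned with limma-voom, which called it in the opposite direction (-8.19, adjusted p = 0.0344), without code set 1 (-3.34, adjusted p = 0.770) and to -1.94 without the low-light 2 mM replicate 2. Camera made no call for the flavonoid list (adjusted p = 0.119) or for the lists that follow, with genes of positive and negative difference, first over all genes and then adjusted over the list alone. Photoprotection had 0 and 1 of 17 (1 and 1), shade avoidance 1 and 0 of 13 (1 and 0), sugar starvation 0 and 1 of 15 (0 and 1) and starch 1 and 0 of 15 (3 and 0). The clock, senescence, phosphate starvation, cytokinin, sulfur, floral transition, epidermis, guard and myrosin cell and vascular lists had 0 genes past the test over all genes and 0 adjusted over the list alone. In this order edgeR gave 0, 0, 4, 2, 1, 1, 0, 0 and 1 at unadjusted p under 0.05. At adjusted p under 0.05 DESeq2 gave 0 in each and limma-voom 0, 4, 2, 1, 1, 1, 1, 0 and 1. The median and mean differed in sign for photoprotection (0.27 and -0.05) and shade avoidance (0.0942 and -0.00393), and for shade avoidance and cytokinin response camera pointed down and fry up.

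**Figure D4:**
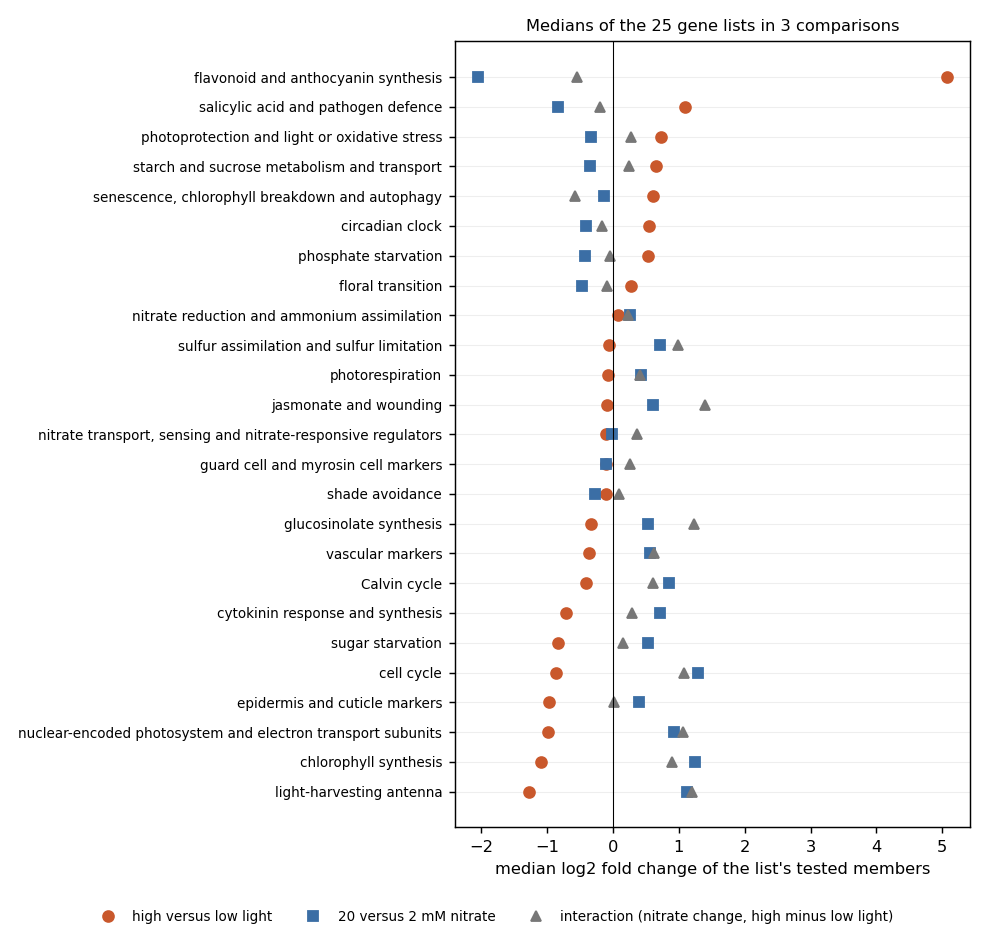
Points give the median log2 change of the tested members of each of the 25 fixed gene lists (vertical axis) for high against low light, 20 against 2 mM nitrate and the difference of the nitrate change between high and low light (colours as in the legend). The flavonoid list lies at 5.07 for light and -2.05 for nitrate, and the photosystem list at -0.98 for light and 0.93 for nitrate.

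Taken light level by light level, 20 against 2 mM called 1695 genes in low light (690 higher, 1005 lower), 8935 in mid light (4128 higher, 4807 lower) and 9913 in high light (4819 higher, 5094 lower). The majority turned in low light with the compared groups alone (897 higher, 739 lower) and without code set 1 (793 and 653). In high light it turned with RLE factors (5107 and 4673), with DESeq2 (5266 and 4833) and without code set 1 (5092 and 4364), and within sets 1, 2 and 4 (2582 and 1927, 709 and 255, 1143 and 1028). In mid light it turned within sets 1, 2 and 3 (762 and 511, 4840 and 3926, 1260 and 1119). Over the 12343 genes called for nitrate on average, the median absolute log2 change was 0.34, 0.62 and 0.66 in low, mid and high light. Photosystem genes rose in 0 of 31 cases in low, 31 in mid and 31 in high light, the same adjusted over the list alone. In low light edgeR gave 2 at unadjusted p under 0.05, and at adjusted p under 0.05 DESeq2 gave 0 and limma-voom 2. Flavonoid genes fell in 3, 18 and 14 of 22 cases (5, 18 and 15 adjusted over the list alone, with 1 that rose in low light). Genes called in low and in high light overlapped in 551 that rose and 773 that fell, against 171 and 263 for independent lists of these sizes. High against low light called 8357 genes at 2 mM (4282 higher, 4075 lower) and 737 at 20 mM (466 higher, 271 lower). The majority turned at 2 mM with RLE factors (4113 and 4295), with DESeq2 (4263 and 4486), without code set 1 (5152 and 5155) and within each code set (156 and 295, 2685 and 3172, 2435 and 2672, 340 and 451), and at 20 mM with the compared groups alone (449 and 468). At 20 mM flavonoid genes still rose in 15 of 22 cases (18 adjusted over the list alone). Photosystem genes passed in 0 of 31, also 0 adjusted over the list alone, by edgeR (1 at unadjusted p under 0.05). At adjusted p under 0.05 DESeq2 gave 0 and limma-voom 1 of them. Within code sets 1 to 4 the nitrate counts were 63, 0, 0 and 0 in low light, 1273, 8766, 2379 and 0 in mid light and 4509, 964, 7015 and 2171 in high light. The light counts were 451, 5857, 5107 and 791 at 2 mM and 0, 778, 29 and 3 at 20 mM. Where these counts were 0, edgeR gave 1697, 3734 and 1317 genes at unadjusted p under 0.05 in sets 2, 3 and 4 in low light, 1959 in set 4 in mid light and 1134 in set 1 at 20 mM. The low-light count was 859 without the low-light 2 mM replicate 2 and 796 without the low-light 20 mM replicate 5, and the 20 mM count 1355 and 397 without the low-light 20 mM replicates 1 and 4. With a replicate block these counts were 3271 and 1890.

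The test of the difference called 604 genes with a difference of at least 2-fold upward and 175 downward, and a test of all 6 interaction terms at once called 2480 genes. Camera made 9 list calls and fry 2 of 25. Under permuted light labels camera made a median of 6 calls. Camera with an estimated correlation made 0 at adjusted p under 0.05 and 2 at unadjusted p under 0.05. Within code sets 1 to 4 the difference between high and low light was called in 0, 5, 1792 and 0 genes (2014 and 2259 at unadjusted p under 0.05 by edgeR in sets 1 and 4) and the 6 terms in 0, 1980, 310 and 0 genes (1668 and 1537 at unadjusted p under 0.05 in sets 1 and 4). The 1175 calls became 2009 without the high-light 20 mM replicate 4, 2436 without the low-light 2 mM replicate 2, 3043 without code set 1 and 2305 with a replicate block, and the 2480 calls 4196 and 4610 in these last settings.

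Averaged over the other factor, light and nitrate changed many of the same genes in opposite directions. Light called 8357 genes at 2 mM but 737 at 20 mM, and nitrate 9913 in high but 1695 in low light. A shift in the groups with high light and low nitrate alone would also give opposite averages. This was not told apart from separate opposing responses. Of 8821 genes called for both, 8479 (96.1%) went opposite ways. Genes that rose with light and fell with nitrate numbered 4532, against 2282 for independent lists of these sizes, and genes that fell with light and rose with nitrate 3947 against 1606, while 190 rose with both against 1893 and 152 fell with both against 1936. DFR, CHS and GLN1;4 were among the first of these groups and RBCS1A, LHCB2.1 and NIR1 among those that fell with light and rose with nitrate. Across all 19498 genes, which are not independent replicates, the light and nitrate changes had a Pearson correlation of -0.80, and of -0.68, -0.71, -0.71 and -0.61 within code sets 1 to 4. Both changes come from the same libraries, and simulated genes with no change gave a correlation of 0.035. That simulation lacks the variation that libraries share, and permuted labels gave a median absolute correlation of 0.31 (light) and 0.43 (nitrate), with 0.645 as the largest.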

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

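The test of code set 1 in low light and all permuted splits were chosen only after the result was seen.

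In groups of 8, a library was noted when its gap to the nearest other library exceeded 0.53 of the group's range. For normally distributed values chance gives this in about 1 of 20 groups. CPM of single genes was not log-transformed here and is skewed, so chance can give it more often. Of 108 group tests 27 passed this cut-off. Total counts of the mid-light 10 mM replicate 2 (ratio 0.565), the low-light 20 mM replicate 4 (0.582) and the mid-light 20 mM replicate 5 (0.577) stood apart, as did the chloroplast-encoded share of the high-light replicates 8 at 2 mM (0.542) and 10 mM (0.583).

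PR1 stood apart most often. Its ratio was 0.994 in the low-light 2 mM replicate 2 (228 CPM against 1.33 in the next library), 0.998 in the low-light 10 mM replicate 2 (209 against 0.473 CPM), 0.973 in the high-light 20 mM replicate 4 (665 against 17.6 CPM), 0.963 in the mid-light 5 mM replicate 2 (70 against 2.6 CPM), 0.905 in the low-light 20 mM replicate 1, 0.718 in the low-light 5 mM replicate 1 and 0.636 in the high-light 10 mM replicate 3. CHS stood apart in the low-light replicates 1 at 5 mM (0.939, 410 against 36 CPM) and 10 mM (0.727), the low-light 20 mM replicate 5 (0.610), the high-light 2 mM replicate 1 (0.677) and the mid-light 2 mM replicate 6 (0.592).

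The mid-light 2 mM replicate 7 stood apart for NIA1 (0.875), ASN1 (0.823, 349 against 62.5 CPM) and RBCS1A (0.692), and the high-light 10 mM replicate 8 for RBCS1A (0.813, 27070 against 8537 CPM) and NIR1 (0.775, 699 against 233 CPM). The other cases were RBCS1A in the high-light 2 mM replicate 8 (0.545), NIA1 in the high-light replicates 2 at 2 mM (0.660) and 5 mM (0.548), ASN1 in the low-light 20 mM replicate 8 (0.536) and NRT2.1 in the high-light 10 mM replicate 2 (0.920).

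The nitrate response differed between high and low light in 1175 genes, and 2480 genes passed the test of all 6 interaction terms. The 1175 became 2009 without the high-light 20 mM replicate 4 and 2436 without the low-light 2 mM replicate 2. The difference in log2 change was positive for TPS10 (6.59), UMAMIT36 (5.99), VSP1 (5.94), VSP2 (3.89), LBD38 (3.12), NIR1 (3.1), NIA1 (2.95), MYB34 (2.74), MYB29 (2.39), LBD37 (2.32), HHO2 (2.18), AOS (1.90), LOX2 (1.88), LHCB2.1 (1.83), LHCB3 (1.75), GLT1 (1.71), GUN4 (1.66), PSAE1 (1.39), UGT74C1 (1.31), LHCB1.5 (1.23), PSAD1 (1.16), PIF4 (1.07) and GLK1 (0.75). It was negative for GLN1;4 (-3.59), ABCB21 (-3.37), ELIP1 (-3.36), F3'H (-3.26), OPT1 (-3.12), PRODH1 (-2.44) and ICS1 (-1.76).

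The nitrate response was smaller in low light, with 1695 genes called against 9913 in high light, and 72.9% of all tested genes had the larger nitrate change, whatever its sign, in high light. The count was 859 without the low-light 2 mM replicate 2 and 796 without the low-light 20 mM replicate 5. A larger spread between low-light libraries is excluded, as their coefficient of variation was 0.384, below 0.464 in mid and 0.431 in high light. Depth is excluded, since with all libraries thinned to 9.46 in units of 1000000 counts, 1482 genes were called in low, 7274 in mid and 8503 in high light, and so is code set 1 as the cause, since without it 1446 genes were called in low against 9456 in high light. The direct test of the difference between high and low light called 1175 genes, and 1129 of these (96.1%) had the larger nitrate change in high light. The light level itself, the difference between these groups in the design, stays open as an explanation. How it would act was not tested.

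Permuted labels gave smaller counts in each of the 14 gene counts of the report. The count was as large in 1 of 25 splits, the real one. This argues against chance labels, but 1 of 25 is the smallest share that 25 splits can give, so chance is not excluded. Under permuted labels the real effect also adds to the spread within groups, which can lower the counts. Permuted light labels remove the light effect too, so they do not test the interaction alone. For 20 against 10 mM the count was 0 without code set 1. The highest other count against the real one was 21 against 12192 for high against low light, 829 against 3854 for mid against low, 8 against 7554 for high against mid, 854 against 12343 for 20 against 2 mM, 125 against 1470 for 5 against 2 mM, 50 against 2735 for 10 against 5 mM and 23 against 214 for 20 against 10 mM. It was 40 against 1695, 559 against 8935 and 983 against 9913 for 20 against 2 mM in low, mid and high light, 359 against 8357 and 3 against 737 for light at 2 and 20 mM, 25 against 1175 for the difference and 147 against 2480 for the 6 terms. Genes called for both light and nitrate numbered 8821 against 11 at most in other splits (1 of 25). For the gene lists camera called 12 for light against 10 in the highest other split (1 of 25). For nitrate 3 of 25 splits gave 10 or more calls (highest 13), and for the difference 5 of 25 gave 9 or more (highest 12). In these last comparisons permuted labels thus reached the real number of list calls. Chance cannot be excluded as the source of that number, and the splits do not argue against it. The strength of single lists was not compared with the splits. The median of the other splits was 6.5 list calls for light, 6.5 for nitrate and 6 for the difference. Camera at its preset correlation thus often called lists under permuted labels.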

How the results depend on the processing

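The tests without code set 1 and without single libraries were chosen only after the result was seen.

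Over the settings planned before the data were examined, 88 values of counts and shares stayed within 1.5 times or kept their call and 29 counts moved further. Among 134 pairs of a named gene and a comparison, 127 kept direction and call in every planned setting. RLE factors, no low-count filter and the log2-level trend moved 0 counts by over 1.5 times and changed 0 calls of named genes, but with RLE the majority of higher or lower genes turned in 4 comparisons, given in the report. RLE moved the median change of all genes by under 0.1. The low-depth alternative left out 0 libraries, since none held under 6.245 in units of 1000000 counts, so it gives no value. Where a count moved, the cause was not tested, except that leaving out libraries and fitting the compared groups alone use fewer samples.

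The numbers 1 to 8 do not pair the plants: deviations from group means had a mean correlation of 0.03 to 0.40 within a number, with negative pairs in each, and 27 of 96 libraries were closest to one of their own number, 66 of 96 to one of their own code set. With a replicate block the counts were 5832 for mid against low light, 3463, 4776 and 1066 for the nitrate steps 5 against 2, 10 against 5 and 20 against 10 mM, 3271 for nitrate in low light, 1890 for light at 20 mM, 2305 for the difference and 4610 for the 6 terms, and with a code set block 5915, 3586, 4852, 1195, 3386, 1996, 2367 and 4899. Limma-voom gave 8668, 5423, 5167, 3110, 4212, 2725, 6842 and 10036. Against these stand 3854, 1470, 2735, 214, 1695, 737, 1175 and 2480. DESeq2 called 450 genes (116 higher, 334 lower) for 20 against 10 mM, and the compared groups alone gave 745 for 5 against 2 mM. Camera with an estimated correlation called 0 lists in each of the 3 comparisons, with 3, 1 and 2 at unadjusted p under 0.05, where fry called 18, 20 and 2.

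Without code set 1 the counts were 6834 for mid against low light, 4187 for 5 against 2 mM, 2150 for light at 20 mM, 3043 for the difference, 4196 for the 6 terms and 0 for 20 against 10 mM (2779 at unadjusted p under 0.05 by edgeR, 3262 with all libraries). Without single libraries the counts ran from 561 (low-light 2 mM replicate 2) to 3116 (mid-light 2 mM replicate 7) for 5 against 2 mM, with 2755 without the low-light 5 mM replicate 1 and 2536 without the mid-light 5 mM replicate 2. They ran from 1227 (high-light 10 mM replicate 8) to 3998 for 10 against 5 mM, with 1761 without the mid-light 5 mM replicate 2, from 796 (low-light 20 mM replicate 5) to 2339 for nitrate in low light, with 859 without the low-light 2 mM replicate 2, from 397 (low-light 20 mM replicate 4) to 1355 (low-light 20 mM replicate 1) for light at 20 mM, and from 900 to 2436 (low-light 2 mM replicate 2) for the difference, with 2009 without the high-light 20 mM replicate 4. For 20 against 10 mM they were 105, 117, 121 and 133 without the low-light 20 mM replicates 5 and 8 and 10 mM replicates 1 and 2, 123 without the mid-light 10 mM replicate 2, 134 without the high-light 10 mM replicate 2, 344 without the high-light 20 mM replicate 4, 368 without the low-light 20 mM replicate 1, 378 without the mid-light 20 mM replicate 5 and 1371 without the high-light 10 mM replicate 8.

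Signs reversed for 2 genes that did not pass with all libraries in edgeR. NRT2.1, near the floor, went from -0.10 for nitrate to 0.094 with limma-voom and 0.12 without code set 1. PR1 went from -1.56 for nitrate to 1.16 without code set 1, with -3.18 (high-light 20 mM replicate 4) to 0.75 (low-light 2 mM replicate 2) without single libraries, and for the difference from 5.06 to -8.19 with limma-voom, a call in the other direction (adjusted p = 0.0344), and -3.34 without code set 1, with -1.94 (low-light 2 mM replicate 2) to 8.18 (low-light 20 mM replicate 1) without single libraries. Other calls that changed were PR1 for light, which passed with a replicate block (4.19), a code set block (3.92), limma-voom (4.69) and without code set 1 (9.92), PR1 for nitrate with a code set block (-1.99), NRT2.1 for light with limma-voom (-1.17), RBCS1A for the difference with limma-voom (1.22), and ELIP1 for the difference, which did not pass with limma-voom (-2.11), in the compared groups alone (-3.38) or without code set 1 (-1.27).

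At this depth the simulated difference between high and low light was found in 17.9% of genes changed by a log2 of 0.5 and 90.9% of those changed by 2, so small interactions are missed more often than small light changes, found in 85.1%. That simulation lacks the variation that libraries share.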

Other observations

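The comparisons of code sets, the tests of depth, time of day, chance labels on a shared axis and the axis of variation between plants were chosen only after the result was seen.

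Code set 1 stood apart from the other 24-library sets. Between it and the rest 13245 genes passed (7315 higher, 5930 lower in set 1), against 229, 2957 and 7921 for sets 2, 3 and 4. Each set was compared with all the others, so set 1 is part of the reference for sets 2 to 4, and these counts are not independent. All 20 antenna genes, 31 of 31 photosystem genes and 13 of 13 cell cycle genes were lower in set 1, while 10 of 13 salicylic acid, 13 of 17 photoprotection and 17 of 22 flavonoid genes were higher (3 photoprotection and 3 flavonoid genes were lower). Also lower were 5 of 6 epidermis and cuticle markers (median -0.90), with PDF1 (AT2G42840) at -6.60, and 6 of 7 guard and myrosin cell markers (median -0.79). The mean mitochondrial share was 0.219% in set 1 and 0.162%, 0.159% and 0.199% in sets 2 to 4. Whether the sets differed in tissue make-up or RNA quality was not tested and stays open. The median total of set 1, 12.46 in units of 1000000 counts, lay within the range of the other sets. Its mean of 13.25 lay above their means of 12.66, 12.91 and 12.76. The sets were not compared at equal depth, so depth as a part of the cause stays open. The organelle share is excluded as the whole cause, since 11721 genes still passed with both shares as covariates. Another time of day at sampling cannot be told apart from other differences between the sets: morning minus evening clock genes were 1.55 higher (log2) in set 1 than in the others (permutation p = 1e-05, the smallest possible), but sets 2 to 4 also differed among themselves (set means 1.16 in set 1, then 0.63, -0.78 and -1.02), and no sampling time is given in the sources used here.

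Averaged over the other factor, the light and nitrate changes were mirror images, with r = -0.80 over 19498 genes and -0.76 without code set 1. A shift in the groups with high light and low nitrate alone would also give a negative r, and no value here tests that. Permuted labels gave an absolute r of 0.645 at most, though these values are far from 0. This argues against chance labels on a shared axis as the whole cause. With 25 splits per factor, the real one included, it does not exclude them. With both organelle shares as covariates r was -0.62. With light and nitrate changes taken from different libraries r was -0.67 and -0.75, which argues against noise shared within libraries as the whole cause. No value without a real change was computed for these splits, so a part is not excluded. No biological explanation was tested.

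Libraries of one group also varied along the same axis. The first component of the residuals, from a fit with both group and code set, held 24.1% of their variance, and its gene weights correlated with the light changes at 0.58 and with the nitrate changes at -0.66. This is what one axis shared by libraries and treatments would give, and the genes are not independent replicates. The differences between code sets, which that fit takes out as additive terms, lay on this axis too, with r of 0.52 with light and -0.57 with nitrate for set 1 and -0.51 and 0.53 for set 4. Each set was compared with all the others, so set 1 is part of the reference for set 4, and these values are not independent. What moves libraries of one group along this axis was not tested.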
